A study of Homo sapiens with 10 samples.

How the data were processed

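Polyadenylated RNA was measured in HEK293FT cells that carried integrated Gaussia and Cypridina luciferase reporters. The cells, 125000 per well, were transfected 1 day after plating with 59 ng of plasmid for dCas9-VP64, a catalytically inactive Cas9 fused to a transcriptional activator, and RNA was taken 3 days later. Where a guide was given, its plasmid was added at 11.6 ng; 679.4 ng of carrier plasmid and 2.25 uL of Lipofectamine were used. The 10 libraries fall into 5 groups of 2, and groups were taken from the sample labels: dCas9-VP64 alone (CasVP) or with the guide labelled sgRNA, INT, P4P6 or TOP1. The labels do not say what distinguishes the INT, P4P6 and TOP1 guides, and the guide TOP1 is not the gene TOP1. They also do not say whether the libraries of a group came from separate cultures, so each p-value measures the spread between these samples only. Each value column names its group and an index of 0 or 1; the index was not matched to the labels' replicate numbers, and libraries are named here by group and index (sgRNA replicate 0).

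The deposited values are FPKM (fragments per kilobase of transcript, scaled by the fragments mapped in each library), 1 column per library. Per the submitters' processing notes, TopHat2 2.0.13 and Cuffdiff 2.2.1 were used with the genome build hg19; the step each tool performed, the annotation and the scaling between libraries are not given there. The upper quartile of FPKM was nearly equal in all libraries, between 17.3 and 17.7. Of 20246 features, 19301 had a gene name; the 945 unnamed ones, 2.31 to 2.47% of summed FPKM, were left out. The named features include 7 construct transcripts: both reporters, dCas9-VP64 and the 4 guides. Of the named features, 2324 were at 0 in every library. Among the tested features, 231 shared a name with another and 509 named several genes.

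Read counts are not part of the values used here. Relative depth was estimated from features with a mean FPKM of at most 0.05, where low values step by single fragments. At the estimated depths, 75.0% of 8314 such values were whole multiples of the lowest step within a tolerance of 0.05. The total of about 28500000 fragments in CasVP replicate 0 is an estimate from transcript lengths of 246 features, with an interquartile range of 25300000 to 30000000.

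Values were log2-transformed after adding a pseudocount of 1 to the authors' FPKM, and features with a mean FPKM of at least 1 over all libraries were tested (11574, of which 11570 are endogenous). Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, a mean for each group and all libraries in the same fit (5 residual degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Each guide was compared with CasVP, each other guide with sgRNA, and all guides with CasVP. The 2 luciferase transcripts were also compared between guides and CasVP with a two-sided exact permutation test over the 45 ways to choose 2 of 10 libraries; 2 libraries against 2 allow no p under 0.333. Each simulated run changed 50 genes at each of the sizes 0.25, 0.5, 1 and 2 on the log2 scale, all in the same run. Of these, 26 to 36% of changes of 0.25 were called, 90 to 98% of changes of 0.5, and 98 to 100% of changes of 1. Noise was drawn independently for each gene. Variation shared between genes was not simulated, so these rates may be too high for the data, as may the larger changes in the same run make them.

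There were 22 gene lists fixed before the data were examined, and the 13 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists in a comparison (104 list comparisons in all). These 13 lists cover interferon-stimulated genes, NF-kappaB targets, p53 targets, the unfolded protein response, heat shock, immediate early genes, sterol synthesis, hypoxia and glycolysis, the cell cycle, ribosomal proteins, the nuclear-encoded respiratory chain, replication-dependent histones and genes typical of HEK293 cells. Estimated correlations and fry were alternatives. A per-library score, the mean deviation of a list's log2 values from each gene's mean, was compared by the exact permutation test.

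The comparisons, main tests, lists and most alternatives were fixed before the data were examined. Genes are named by a rule from the same time. It takes all construct transcripts and, per comparison, up to 12 genes each way with the largest change among those that passed with no overlap between groups. If fewer than 10 passed, the rule adds 5 genes each way with a mean FPKM of at least 5 and no overlap that did not pass. It also takes up to 4 members per list with the largest change in any guide against CasVP, and the gene TOP1. Alternatives fixed at that time were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios rescaling, quantile normalization, a replicate block, no trend, library weights, the libraries of 2 groups only, and each library left out. Length and GC content from GENCODE 29 were matched by symbol for 85.8% of tested features, because its coordinates belong to another genome build. Removing each library's trend on both was chosen after seeing the data, as were the Gaussia to dCas9-VP64 ratio, list scores, list values with a library left out, list medians under each scaling and splits of the p53 score by index. Quantile normalization gives every library the same highest values. Because 37 of the 40 ribosomal protein genes are among the 100 most abundant features, it takes their shared differences to about 0 by construction and is not used for that list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.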

Results

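RNA was sequenced from HEK293FT, a readily transfected line derived from human embryonic kidney cells, after delivery of the dCas9-VP64 activator alone (CasVP) or with 1 of 4 guides directed at an integrated Gaussia luciferase reporter. The guides are labelled sgRNA, INT, P4P6 and TOP1, and each of the 5 groups has 2 libraries. An integrated Cypridina luciferase reporter serves as a normalizer. Estimated depth ranged from about 19700000 fragments in P4P6 replicate 0 to 28900000 in TOP1 replicate 0. Pearson's r of log2(FPKM + 1) across genes was 0.994 to 0.998 within groups and 0.991 to 0.998 between groups, where genes are not independent replicates. The SD of the log2 difference between replicates was 0.104 in CasVP, 0.136 in sgRNA, 0.141 in INT, 0.138 in TOP1 and 0.188 in P4P6. Along the first principal component, with 34.0% of the variance, the P4P6 libraries stood at 6.06 and 15.5, above all others.

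The Gaussia reporter, the target of the guides, passed in every comparison of a guide with CasVP, with the largest change among the transcripts that passed. It stood at 23.3 FPKM with the activator alone (SD 0.759, n = 2) and at 822 with sgRNA (SD 49.5, n = 2), 35.3 times as high. INT brought it to 361 FPKM (SD 7.33, n = 2), TOP1 to 265 (SD 11.2, n = 2) and P4P6 to 176 (SD 18.5, n = 2), or 15.5, 11.4 and 7.55 times the level in CasVP. Levels with these 3 guides were 43.9%, 32.2% and 21.4% of that with sgRNA. On the log2 scale the rise over CasVP was 5.08 with sgRNA (limma adjusted p = 6.73e-11), 3.90 with INT (9.66e-10), 3.45 with TOP1 (3.27e-09) and 2.86 with P4P6 (2.17e-08), each with an SE of 0.07. Against sgRNA, the Gaussia transcript differed by -1.18 with INT (adjusted p = 0.000139), -1.63 with TOP1 (5.97e-06) and -2.22 with P4P6 (2.71e-07). Over the 4 guides together the difference from CasVP was 3.82 (two-sided exact permutation p = 0.0222, the smallest that 45 splits of 10 libraries can give). The highest difference among other splits was 2.53.

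Cypridina luciferase, which the guides do not target, was close to the filter on low values. Its mean was 1.27 FPKM in CasVP (SD 0.172, n = 2), 1.5 with sgRNA (SD 0.165), 1.74 with INT (SD 0.411), 1.63 with P4P6 (SD 0.120) and 1.08 with TOP1 (SD 0.0930). The guides together differed from CasVP by 0.12 on the log2 scale (limma SE 0.09, 95% confidence interval -0.08 to 0.33, adjusted p = 0.807). The two-sided exact permutation p was 0.422. The difference was 0.198 without CasVP replicate 0, 0.0431 without CasVP replicate 1 and 0.187 with a pseudocount of 0.1.

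The dCas9-VP64 transcript, which encodes the activator, was at 14.7 FPKM in CasVP (SD 0.115, n = 2), 23.7 with sgRNA (SD 0.463), 25.7 with INT (SD 0.238), 18.6 with P4P6 (SD 2.08) and 16.6 with TOP1 (SD 0.745). It rose by 0.65 on the log2 scale with sgRNA (limma adjusted p = 0.0153), by 0.77 with INT (0.00341) and by 0.47 over all guides (0.0325). It was lower with P4P6 than with sgRNA (log2 difference -0.34, adjusted p = 0.025). The differences from CasVP with P4P6 (0.32, adjusted p = 0.075) and TOP1 (0.16, adjusted p = 0.533) did not pass. Nor did INT against sgRNA (0.11, adjusted p = 0.629) or TOP1 against sgRNA (-0.49, adjusted p = 0.195). These calls were fragile, but the size of the rise with sgRNA or INT rests on libraries that lie close together. The sgRNA libraries were at 24.0 and 23.4 FPKM and the INT libraries at 25.6 and 25.9, against 14.8 and 14.6 in CasVP. With sgRNA the call ended without either CasVP library or either sgRNA library, each of which leaves a group with 1 library. It also ended without the filter (adjusted p = 0.117) and without the trend (0.0508). With INT the call ended without either CasVP library or either INT library. The call for all guides ended without the filter (0.216), without the trend (0.0992), and when any library outside P4P6 was left out (0.0647 to 0.791). P4P6 against sgRNA lost its call without P4P6 replicate 1 or either sgRNA library, and with the libraries of these 2 groups only (adjusted p = 0.0968). Both P4P6 libraries, at 17.1 and 20.1 FPKM, lay below both sgRNA libraries. P4P6 against CasVP gained one without P4P6 replicate 0 (0.0167) and with a replicate block (0.0378).

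**Figure D1:**
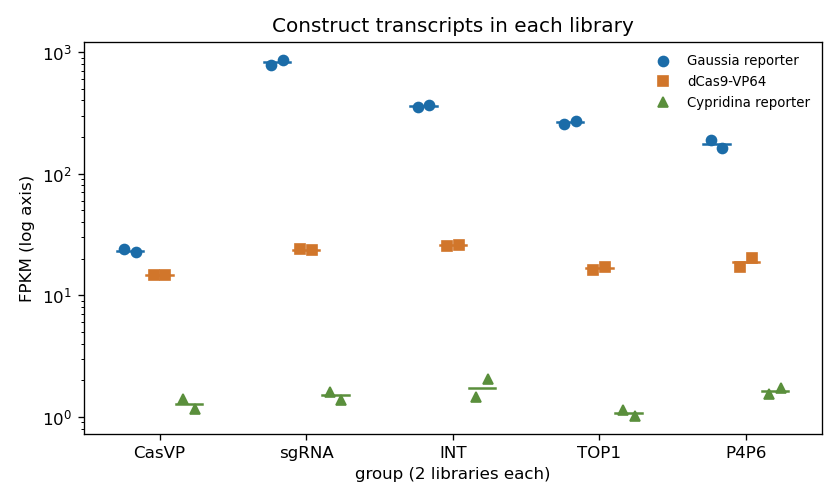
FPKM (log axis) of the Gaussia reporter, dCas9-VP64 and Cypridina reporter transcripts in each of the 10 libraries by group, with points for libraries and lines for group means. Mean Gaussia FPKM runs from 23.3 in CasVP to 822 with sgRNA, while mean Cypridina FPKM lies between 1.08 and 1.74.

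The comparison of sgRNA with CasVP asks what the guide labelled sgRNA changed in the cells beyond the reporter. Of 11570 endogenous genes tested with limma, 0 passed, with 697 of all 11574 features at an unadjusted p under 0.05. The 2 features that passed were the Gaussia and dCas9-VP64 transcripts; the count was 1 without CasVP replicate 0, sgRNA replicate 0 or sgRNA replicate 1, without a filter or without the trend, and 4 with the libraries of these 2 groups only. Among the genes with the largest estimates, none of which passed, NEDD4L, a ubiquitin ligase, stood at 11.6 FPKM against 4.70 in CasVP (SD 3.59 and 0.0742, n = 2 each). The cytokine gene MIF stood at 86.6 against 44.4 FPKM (SD 4.66 and 11.9), and ARRDC3, an arrestin-domain gene, at 6.03 against 3.58 (SD 1.89 and 0.705). INHBE, which encodes an inhibin beta subunit, was at 7.11 against 11.3 FPKM (SD 0.213 and 1.38), and RECK, an inhibitor of matrix metalloproteinases, at 6.65 against 9.09 (SD 1.82 and 1.21). C19orf60, CCDC85B, AFF1, C3orf21 and PCMTD1 had log2 estimates of 0.60, 0.56, -0.70, -0.52 and -0.43. Estimates of 98.6% of endogenous genes had a 95% confidence interval within 1.5-fold of no change in FPKM + 1. For genes near the filter that bound allows a larger fold in FPKM itself. Of the 11574 tested features, 9127 had a mean FPKM of at least 5. Libraries of sgRNA and CasVP did not overlap for 46.0% of genes, where chance gives 33.3%.

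Among the lists, p53 target genes had estimates above 0 for 25 of 25 members with sgRNA (median log2 change 0.17, camera adjusted p = 1.59e-09), yet 0 members passed over all genes and 1 rose when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.322). FDXR, a mitochondrial reductase gene and p53 target, was at 17.6 against 12.6 FPKM (SD 2.46 and 1.08). The 40 ribosomal protein genes had a median of 0.09 with sgRNA (camera adjusted p = 1.99e-09; adjusted p = 0.379 with an estimated correlation). For the 37 nuclear-encoded respiratory chain genes the median was 0.07 (6.82e-06; adjusted p = 0.322 with an estimated correlation), which was 0.00 under quantile normalization. RPS15 and RPLP2 stood at log2 estimates of 0.34 and 0.33, and COX8A and NDUFS6 at 0.41 and 0.29, without passing. No member of either list passed over all genes or adjusted over the list alone.

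INT and CasVP were compared in the same way. With limma, 0 endogenous genes passed (1026 of 11574 features at an unadjusted p under 0.05), and the 2 features that did were again the Gaussia and dCas9-VP64 transcripts. The dCas9-VP64 call ended when any library of the 2 groups was left out. Without CasVP replicate 1, INT replicate 0 or INT replicate 1, another feature passed in its place. BTG2 and PHLDA3, both p53 targets, were at 14.4 against 9.82 FPKM (SD 2.61 and 0.415) and 17.0 against 11.4 (SD 2.69 and 0.758), without passing (adjusted p = 0.507 for each). TPM2, a tropomyosin gene, was at 9.91 against 6.72 FPKM (SD 1.80 and 0.489). INHBE had 7.23 against 11.3 FPKM (SD 1.41 and 1.38) and did not pass either. Log2 estimates of ARRDC3 and the joint ACTB,ACTG1 feature were 0.60 and 0.47; those of IFI27L2, RECK, KRTAP19-1 and C1orf182 were -0.52, -0.48, -0.41 and -0.41. Libraries of the 2 groups did not overlap for 43.4% of genes against 33.3% by chance.

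With INT, 21 of 25 p53 targets had estimates above 0 (median 0.19, camera adjusted p = 2.80e-08; adjusted p = 0.416 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of -0.14 (camera adjusted p = 0.0117; adjusted p = 0.416 with an estimated correlation). HIST1H4E, with the largest estimate of that list, stood at 0.825 against 1.99 FPKM (SD 0.0622 and 0.792). The histone call ended without INT replicate 0 (adjusted p = 0.183). Small shifts also passed for ribosomal protein genes (median -0.05, adjusted p = 0.0165) and respiratory chain genes (-0.06, adjusted p = 0.0165). With an estimated correlation these gave an adjusted p = 0.607 and an adjusted p = 0.416. The ribosomal call ended without CasVP replicate 0 or INT replicate 1. The per-library score of that list was 0.00279 in INT replicate 0 and -0.0857 in INT replicate 1, against 0.0122 and -0.00201 in CasVP. The shift therefore rests mainly on INT replicate 1. The respiratory chain call ended without CasVP replicate 1 (0.163) or INT replicate 1 (0.373); 0 of its genes passed over all genes and 2 were lower when adjusted over the list alone. No histone or ribosomal protein gene passed in either way.

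P4P6 against CasVP gave 1 feature that passed, the Gaussia transcript, and 0 endogenous genes with limma, although 2568 of 11574 features had an unadjusted p under 0.05. FASN, which encodes fatty acid synthase, came closest, at 46.8 FPKM against 36.8 (SD 0.296 and 0.599, adjusted p = 0.0689). HES4, a Hes-family repressor gene, was at 27.5 against 16.8 FPKM (SD 2.48 and 1.44), and the ribosomal protein gene RPS20 at 891 against 1275 (SD 73.0 and 376). NDUFB2, a subunit gene of respiratory complex I, was at 162 against 204 FPKM (SD 12.0 and 14.2), and COX6A1, of cytochrome c oxidase, at 601 against 722 (SD 19.5 and 1.72); neither passed. Log2 estimates of MIF, PCSK1N, CCDC85B and NEDD4L were 1.04, 0.83, 0.75 and 0.73, and those of RECK, KRTAP19-1, C15orf41 and SLC39A11 were -0.67, -0.57, -0.50 and -0.46. Without P4P6 replicate 0 the count was 764 (230 higher, 534 lower), without P4P6 replicate 1 it was 2, without CasVP replicate 0 it was 3, and with a replicate block it was 600. Quantile normalization gave 7 and removal of length and GC trends 2. Libraries of P4P6 and CasVP did not overlap for 51.6% of genes, with 33.3% by chance.

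Ribosomal protein genes were lower with P4P6 than with CasVP (median -0.20, camera adjusted p = 5.74e-12), with 0 of 40 passing over all genes and 27 lower when adjusted over the list alone. The list call gave an adjusted p = 0.775 with an estimated correlation, and the median was -0.19 with median-of-ratios rescaling. Respiratory chain genes had a median of -0.15 (camera adjusted p = 8.03e-07; adjusted p = 0.343 with an estimated correlation), with 0 passing over all genes and 20 of 37 lower when adjusted over the list alone. Quantile normalization left a median of -0.08 and no call (adjusted p = 0.0916). For p53 targets the median was 0.08 (20 of 25 above 0, adjusted p = 0.124); the list passed without CasVP replicate 0 (adjusted p = 0.0446) or P4P6 replicate 1 (adjusted p = 6.81e-06) and with a replicate block (0.0299).

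In the comparison of TOP1 with CasVP only the Gaussia transcript passed, and 0 endogenous genes did with limma (1067 of 11574 features at an unadjusted p under 0.05). ACYP1, an acylphosphatase gene, was at 31.9 against 22.7 FPKM (SD 1.17 and 1.15), and TMEM160 at 11.4 against 7.47 (SD 4.29 and 0.157). PTCH1, the Hedgehog receptor gene, was at 4.07 against 5.87 FPKM (SD 0.176 and 0.273) and INHBE at 7.32 against 11.3 (SD 1.10 and 1.38). The adjusted p was 0.501 for ACYP1, PTCH1 and INHBE and 0.503 for TMEM160. NEDD4L, ARRDC3 and FDXR had log2 estimates of 0.76, 0.63 and 0.40; AFF1, PCMTD1 and SPR had -0.75, -0.41 and -0.40. The gene TOP1, which encodes DNA topoisomerase 1 and shares only its symbol with the guide, was at 51.7 FPKM (SD 1.74) against 51.6 in CasVP (SD 0.929), 49.7 with sgRNA, 50.5 with INT and 51.0 with P4P6. Libraries of TOP1 and CasVP did not overlap for 48.2% of genes, where chance gives 33.3%. Without CasVP replicate 1 the count was 2, and without a filter it was 3.

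Estimates of p53 targets with TOP1 lay above 0 for 22 of 25 (median 0.15, camera adjusted p = 1.04e-06; adjusted p = 0.501 with an estimated correlation). Ribosomal protein genes had a median of 0.11 (8.17e-09; adjusted p = 0.501 with an estimated correlation). Respiratory chain genes had a median of 0.06 (0.000159; adjusted p = 0.386 with an estimated correlation), a direction that turned under quantile normalization. Cell cycle genes had a median of 0.03 (adjusted p = 0.0438; adjusted p = 0.501 with an estimated correlation). That call ended without CasVP replicate 1 (0.188) or TOP1 replicate 0 (0.183). No gene of these 4 lists passed over all genes or adjusted over the list alone.

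All guides together against CasVP gave 0 endogenous genes with limma (860 of 11574 features at an unadjusted p under 0.05), and the Gaussia and dCas9-VP64 transcripts passed. The count fell from 2 to 1 without CasVP replicate 0, INT replicate 0, TOP1 replicate 0, sgRNA replicate 0 or sgRNA replicate 1, without a filter and without the trend. EXD3, a gene with an exonuclease domain, came closest. It stood at 5.99 FPKM in CasVP (SD 0.205) and at 7.91 to 8.17 in the 4 guide groups (log2 difference 0.37, SE 0.06, adjusted p = 0.297). GADD45A, a DNA damage response gene, was at 40.2 FPKM in CasVP and 49.3 to 51.1 with guides (adjusted p = 0.669). ECE2, an endothelin-converting enzyme gene, was at 16.3 FPKM in CasVP and 12.5 to 13.7 with guides (adjusted p = 0.659). TMEM160, PHLDA3 and TPM2 had log2 estimates of 0.51, 0.41 and 0.41, and INHBE, C3orf21, COMMD1 and BATF3 had -0.51, -0.34, -0.28 and -0.27. CasVP libraries did not overlap the guide libraries for 558 genes, 4.82% against 4.44% by chance. Of p53 targets, 24 of 25 lay above 0 (median 0.15, camera adjusted p = 8.08e-10; adjusted p = 0.557 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Their per-library score was 0.16 higher with guides (two-sided exact permutation p = 0.111; 5 of 45 splits as large, adjusted p = 0.433 over 13 lists). It was above both CasVP libraries in 7 of 8 guide libraries. In every group the score was higher in replicate 0 than in replicate 1. The same held for scores of ribosomal protein, unfolded protein response and NF-kappaB genes, but not for those of the other lists.

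INT was then compared with the guide labelled sgRNA. The Gaussia transcript alone passed, and 0 endogenous genes did with limma (1015 of 11574 features at an unadjusted p under 0.05; without INT replicate 0, or without INT replicate 1, the count was 2). NEDD4L was at 4.61 against 11.6 FPKM (SD 0.0775 and 3.59), and ID1, a helix-loop-helix inhibitor gene, at 5.40 against 7.46 (SD 0.445 and 0.0462). TPM2 was at 9.91 against 7.48 (SD 1.80 and 0.30) and NLGN2, a neuroligin gene, at 16.3 against 13 (SD 0.993 and 0.526); all 4 had an adjusted p of 0.555. Log2 estimates of ACTB,ACTG1, ANKS1A and PCMTD1 were 0.45, 0.35 and 0.32, and those of C19orf60, CFD and ZNF593 were -0.38, -0.38 and -0.37. Estimates of ribosomal protein genes were below 0 for all 40 (median -0.14, camera adjusted p = 1.11e-15; adjusted p = 0.395 with an estimated correlation). Respiratory chain genes had a median of -0.12 (1.61e-11; adjusted p = 0.118 with an estimated correlation), with 0 passing over all genes and 3 of 37 lower when adjusted over the list alone. Quantile normalization left a median of -0.03 (adjusted p = 0.058). Groups did not overlap for 43.0% of genes against 33.3% by chance.

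P4P6 against sgRNA was the comparison in which many endogenous genes passed: 501 were higher and 828 lower with P4P6, beside the lower Gaussia and dCas9-VP64 transcripts. The changes were small, with a median absolute log2 change of 0.25 and a largest of 0.62. In FPKM + 1, 0 of those that passed in limma exceeded 2-fold (3502 of 11574 features had an unadjusted p under 0.05). FASN, the fatty acid synthase gene, rose from 34.1 FPKM (SD 0.932) to 46.8 (SD 0.296), with the smallest adjusted p of any endogenous gene, 0.0119. ZDHHC8, a palmitoyltransferase gene, rose from 11.1 to 16.7 FPKM (SD 0.516 and 1.91). DOT1L, the histone H3 lysine methyltransferase gene, rose from 9.63 to 14 (SD 0.763 and 0.601), and LAMA5, a laminin chain gene, from 3.67 to 5.70 (SD 0.160 and 0.790). The anti-Mullerian hormone gene AMH rose by 0.55 on the log2 scale, and SHISA4, the joint feature PILRA,PILRB, C19orf71 and KREMEN2 by 0.62, 0.61, 0.60 and 0.56. MYPOP, ZNF628, RAB3A and STAT4 rose by 0.52, 0.51, 0.50 and 0.49. Adjusted p for these 12 genes ranged from 0.0221 to 0.0484.

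Downward, CMC1, a cytochrome c oxidase assembly gene, fell from 81.2 FPKM with sgRNA (SD 2.02) to 59.8 with P4P6 (SD 2.31), with a limma adjusted p of 0.0221. ANXA1, an annexin gene, had a log2 change of -0.55 (adjusted p = 0.0339), and SLC39A11, a zinc transporter gene, -0.47 (0.0259). The ribosomal protein pseudogene RPL13AP20 changed by -0.46, the relaxin gene RLN2 by -0.47 and the PACAP receptor gene ADCYAP1R1 by -0.45. C5orf35, PGAM4, DTWD1, C9orf46 and C12orf60 had log2 changes of -0.51, -0.50, -0.48, -0.48 and -0.44.

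Cytoplasmic ribosomal protein genes were lower in all 40 estimates with P4P6 than with sgRNA, with a median of -0.28 (-0.27 with median-of-ratios rescaling and -0.22 after removal of length and GC trends); 33 fell over all genes and 35 when adjusted over the list alone. The list gave a camera adjusted p of 1.14e-17, an adjusted p = 0.496 with an estimated correlation and a fry adjusted p of 0.0144. RPS20, RPS15 and RPLP2 did not pass. Of 37 nuclear-encoded respiratory chain genes, 20 fell over all genes and 25 when adjusted over the list alone (median -0.20, camera adjusted p = 3.81e-11; adjusted p = 0.127 with an estimated correlation; fry 0.00112). Under quantile normalization that median was -0.04, with no call (adjusted p = 0.183). Summed FPKM was 553565 and 535756 in the P4P6 libraries, against 610798 and 601606 in the sgRNA libraries. Whether the fall was particular to ribosomal protein and respiratory chain genes or shared by other abundant transcripts was not tested. NDUFB2 had a log2 change of -0.39 (adjusted p = 0.0231). Of 33 cell cycle genes, 4 fell over all genes, and 1 rose and 8 fell when adjusted over the list alone (median -0.11, camera adjusted p = 0.0493; adjusted p = 0.589 with an estimated correlation), a list whose camera direction turned under quantile normalization. Its call ended without P4P6 replicate 1 (adjusted p = 0.189), sgRNA replicate 1 (0.0549), either CasVP library (0.0507) or either INT library (0.0529). Among 32 genes of the unfolded protein and integrated stress response, 1 rose and 4 fell over all genes and over the list alone, among them ASNS, asparagine synthetase (-0.29, adjusted p = 0.0456). That list did not pass (median -0.05, which turned above 0 under quantile normalization, adjusted p = 0.0858). HSPD1, a mitochondrial chaperonin gene, fell by 0.25 (adjusted p = 0.0318), the 1 of 17 heat shock genes to pass over all genes or adjusted over the list alone. STAT2, an interferon signalling gene, rose by 0.22 (adjusted p = 0.0454), the 1 of 20 interferon-stimulated genes to pass over all genes, with 0 adjusted over the list alone. Of 25 p53 targets, 6 had estimates above 0 (median -0.13, camera adjusted p = 0.0858; adjusted p = 0.861 with an estimated correlation). That list passed, downward, without P4P6 replicate 0 (adjusted p = 0.000276) or sgRNA replicate 1 (0.0106), with a replicate block (0.0211) and after removal of length and GC trends (0.00971). The members that passed over all genes and over the list alone were named after their values were seen. They were the joint p53 feature DDB2,ddb2, lower, and of 23 immediate early genes KLF10, lower. Of 27 hypoxia and glycolysis genes, ENO1 and GAPDH passed, lower. Of the 26 genes of the sterol list, HMGCS1 and IDI1 passed, lower. FASN, the fatty acid synthase gene also on that list, passed, higher. The sterol, hypoxia and immediate early lists did not pass (camera adjusted p = 0.835, 0.840 and 0.911), although sterol genes did, downward, without P4P6 replicate 1 (0.0481).

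Leaving out a library of P4P6 or sgRNA leaves that group with 1. A lower count may then reflect fewer libraries and not the library itself. The count for P4P6 against sgRNA moved with single libraries left out. It was 1331 with all libraries, 2046 without P4P6 replicate 0, 2 without P4P6 replicate 1, and 1 without either sgRNA library. With the libraries of these 2 groups only it was 2. Of these, only the Gaussia transcript had also passed with all libraries, so no named endogenous gene passed in every alternative. With a replicate block the count was 2326. It was 641 without a filter, 668 without the trend, 384 with library weights and 216 after removal of length and GC trends. Quantile normalization gave 388, of which 298 were higher and 90 lower, and median-of-ratios rescaling gave 557 higher and 637 lower, so the share of genes that fell depends on the scaling. Groups did not overlap for 56.5% of genes, where chance gives 33.3%.

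**Figure D2:**
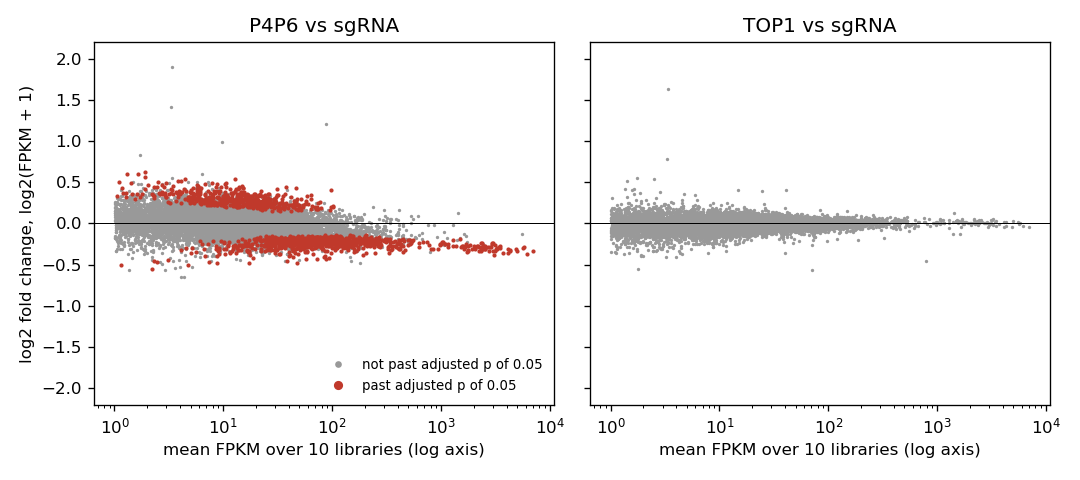
Log2 fold change of each endogenous gene against its mean FPKM over 10 libraries (log axis), for P4P6 against sgRNA and TOP1 against sgRNA, with genes at an adjusted p under 0.05 in red. For P4P6, 501 red points lie above 0 and 828 below, the farthest at 0.62, and 0 points are red for TOP1; quantile normalization turns the split to 298 higher and 90 lower features.

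TOP1 against sgRNA had the lowest number of features at an unadjusted p under 0.05 of all comparisons, 195 of 11574. With limma, 0 endogenous genes passed; the Gaussia transcript alone passed (the count was 3 without a filter and 2 with library weights). ANKS1A was at 15.7 against 11.6 FPKM (SD 0.862 and 1.11) and CENPE, a kinetochore motor gene, at 28.6 against 21.6 (SD 0.543 and 4.17). SERTAD1 was at 4.74 against 6.12 FPKM (SD 0.407 and 0.561). C1orf112, HYI and PCOLCE had log2 estimates of 0.40, 0.35 and 0.28, and ST20, ZDHHC24, YPEL3 and NACAP1 had -0.33, -0.29, -0.28 and -0.27; none passed. Interferon-stimulated genes were lower as a list (median -0.10, 3 of 20 above 0, camera adjusted p = 0.000974; adjusted p = 0.0983 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. That call ended without TOP1 replicate 1 (adjusted p = 0.0825) or sgRNA replicate 0 (0.0787). Groups did not overlap for 29.2% of genes against 33.3% by chance.

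**Figure D3:**
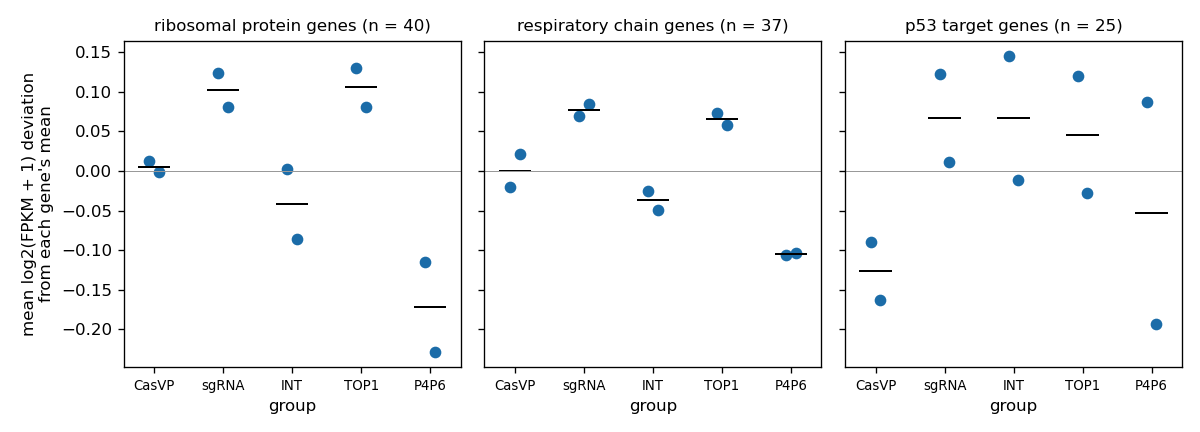
Mean deviation of log2(FPKM + 1) from each gene's mean in each library (points) and group (lines), for 40 ribosomal protein, 37 respiratory chain and 25 p53 target genes. P4P6 libraries are lowest for ribosomal protein genes (-0.11 and -0.23), with a median log2 change from sgRNA of -0.27 under median-of-ratios rescaling, and for p53 targets CasVP libraries lie at -0.09 and -0.16 and P4P6 replicate 1, the lowest, at -0.19.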

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

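The tests of the dCas9-VP64 level and of plasmid uptake, and the bounds set for the planned scalings, were chosen only after the results were seen. The Gaussia transcript stood out because its rise over CasVP differed between guides in the limma test of the difference itself: by -1.18 on the log2 scale for INT against sgRNA, -1.63 for TOP1 and -2.22 for P4P6. The tables argue against the level of the dCas9-VP64 transcript as the whole cause, since guide means of log2 Gaussia over dCas9-VP64 still spanned 1.88 (pooled SD 0.167), from 5.12 with sgRNA to 4.0 with TOP1, 3.81 with INT and 3.24 with P4P6. They argue against scaling too, which left at least 0.905 of the INT difference. The guide given, which the design varies, stays open as a biological explanation, and so does the amount of each guide RNA, which was not tested. A hypothesis is therefore that these 3 guides may direct weaker activation than sgRNA, tested here on the same data in which it was found.

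The dCas9-VP64 transcript was picked out because its change from CasVP was smaller with P4P6 than with sgRNA (limma log2 difference -0.34). That call ended without P4P6 replicate 1, sgRNA replicate 0 or sgRNA replicate 1. P4P6 libraries stood at 17.1 and 20.1 FPKM, below the sgRNA libraries at 24.0 and 23.4. The TOP1 mean was lower still, 16.6 FPKM against 18.6 with P4P6, but TOP1 against sgRNA did not pass. P-values were adjusted within a comparison. An unadjusted limma p under 0.05 was reached by 3502 features in P4P6 against sgRNA and 195 in TOP1 against sgRNA. A call with P4P6 alone therefore does not show that P4P6 and TOP1 differ in the dCas9-VP64 transcript. Its higher level with sgRNA and INT kept 0.996 of the smaller difference under other scalings; whether those wells took up more plasmid cannot be told apart from other causes, since 0 other transcripts of the transfected plasmids were above 0 both in CasVP, which was given no guide, and in both libraries of sgRNA or INT.

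Of the guide transcripts, that of sgRNA alone reached the filter on low values, and it passed in no comparison with all libraries (lowest adjusted p = 0.419, in P4P6 against CasVP). All 4 were listed at 0 in both CasVP libraries. The INT guide was at 1.38 FPKM in INT replicate 0 and at 0 in INT replicate 1. P4P6 had its guide at 0.440 and 0.761 FPKM, and TOP1 at 0.331 and 0.441. The sgRNA guide was at 233 FPKM in sgRNA replicate 0 and at 109 in P4P6 replicate 0, and at 0 in sgRNA replicate 1. Scaled to equal depth, the P4P6 guide in P4P6 replicate 1 was 1.99 times its value in P4P6 replicate 0. The TOP1 guide in TOP1 replicate 0 was 1.03 times its value in TOP1 replicate 1. The sgRNA guide in sgRNA replicate 0 was 2.18 times its value in P4P6 replicate 0. Such steps leave open that 1 or a few fragments lie behind each value, but the number behind the lowest is not known. The 233 and 109 FPKM therefore do not show an abundant guide transcript.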

How the results depend on the processing

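Removing length and GC trends was chosen after seeing the data, as were the Gaussia to dCas9-VP64 ratio, the fit on genes with both length and GC values, and, for lists, the leave-one-out values, scores per library, splits by index and medians under each scaling; the other alternatives were planned. Leaving out a library leaves a group with 1, which is assumed to vary like the others. Over 192 named results, 2883 alternative values were computed: 2636 kept their direction and side of the threshold, 197 lost a call, 30 gained one and 20 turned or fell to 0. Of 36 results that passed, 8 (all Gaussia) did so in every alternative and 0 turned. The difference of the Gaussia transcript between guides and CasVP ranged from 3.35 (over dCas9-VP64) to 3.87, and from 3.79 to 3.86 with a library left out; 1 CasVP library against 8 cannot give an exact p under 0.111, so limma judged those without a CasVP library. As a Gaussia to Cypridina ratio, the Cypridina difference became 3.70 because the ratio holds Gaussia. Except where named, the cause was not tested.

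Counts of changed features moved by over 1.5 times as follows. With no filter they were 1 for sgRNA against CasVP, 3 for TOP1 against CasVP, 641 for P4P6 against sgRNA, 3 for TOP1 against sgRNA and 1 for all guides. Without the trend they were 1 for sgRNA against CasVP, 668 for P4P6 against sgRNA and 1 for all guides. With libraries of the 2 groups only they were 4 for sgRNA against CasVP and 2 for P4P6 against sgRNA. Quantile normalization gave 7 for P4P6 against CasVP and 388 for P4P6 against sgRNA. Library weights gave 384 for P4P6 against sgRNA and 2 for TOP1 against sgRNA. Removing length and GC trends gave 2 for P4P6 against CasVP and 216 for P4P6 against sgRNA. Without each library in turn, counts ranged from 1 to 2 for sgRNA, INT and TOP1 against CasVP and INT against sgRNA, 1 to 3 for all guides, 1 to 764 for P4P6 against CasVP (764 without P4P6 replicate 0) and 1 to 2046 for P4P6 against sgRNA. That last count was 2046 without P4P6 replicate 0, 2 without P4P6 replicate 1 and 1 without sgRNA replicate 0 or 1. Of 31 list calls, 0 held with an estimated correlation and 4 with fry; leaving out a library gave 22 to 36. The 6 calls for ribosomal protein genes all held with median-of-ratios rescaling and after removal of length and GC trends. Under quantile normalization 0 held, which follows from how that method treats the most abundant transcripts. Removing length and GC trends gave 34. Calls were gained by interferon genes in sgRNA against CasVP (0.0440), genes typical of HEK293 cells in INT against CasVP (0.0444), hypoxia genes in TOP1 against CasVP (0.0170) and p53 targets in P4P6 against sgRNA (0.00971), and sterol genes over all guides lost theirs (0.103).

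The replicate block gave 600 features for P4P6 against CasVP and 2326 for P4P6 against sgRNA. List calls rose from 31 to 35 with it: p53 targets passed in P4P6 against CasVP (adjusted p = 0.0299) and P4P6 against sgRNA (0.0211), histone genes in sgRNA against CasVP (0.0261) and over all guides (0.0159), and genes typical of HEK293 cells in INT against CasVP (0.0152), while sterol genes over all guides lost their call (0.0821). Differences between replicates 0 and 1 correlated across genes above 0 in 9 of 10 pairs of groups and above 0.1 in 8, from -0.04 (INT and TOP1) and 0.09 (CasVP and TOP1) to 0.42 (sgRNA and P4P6). A shared source of variation behind the index is therefore not excluded. Unblocked values lead, as no label ties the index to a batch or day, but P4P6 counts depend on this.

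The estimates that turned passed neither with all libraries nor where they turned. FBLN1 in P4P6 against CasVP went from 0.148 to -0.0153 without length and GC trends. The gene TOP1 in P4P6 against CasVP, at -0.0168, was 0.0227 with quantile normalization, 0.00454 without those trends and -0.0936 to 0.0600 with a library left out. For the guide TOP1 against CasVP, this gene, at 0.00361, was -0.000298 with median-of-ratios rescaling, -0.0243 with quantile normalization, -0.0124 without those trends and -0.0300 to 0.0373 with a library left out. In P4P6 against sgRNA, at 0.0341 with all libraries, it ranged from -0.0427 to 0.111. With a library left out, SOX2 in sgRNA against CasVP (-0.0705) ranged from -0.163 to 0.0215, and Cypridina in INT against sgRNA (0.127) from -0.0260 to 0.281. The sgRNA guide transcript was above 0 only in sgRNA replicate 0 and P4P6 replicate 0. In sgRNA against CasVP (3.94) it was 0 without sgRNA replicate 0 and 7.87 without sgRNA replicate 1, and INT and TOP1 against sgRNA (-3.94 each) gave 0 and -7.87. In P4P6 against CasVP (3.39) it was 0 without P4P6 replicate 0 and 6.78 without P4P6 replicate 1. In P4P6 against sgRNA (-0.547) it was 3.39 without sgRNA replicate 0, -4.48 without sgRNA replicate 1 and 2.84 without P4P6 replicate 1.

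Count-based alternatives, a second count model and a test on recovered reads, were not run because the values are FPKM and the fragments behind them were recovered only for low values. Depth limits transcripts near 1 FPKM, such as Cypridina.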

Other observations

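Among tests of explanations, those on p53 targets and the left-out libraries of gene lists were chosen only after the results were seen, and the removal of length and GC trends and the list medians under quantile normalization after the data were seen. Several fixed lists moved little or not as a whole. Immediate early genes, which respond first to growth signals, had a median log2 estimate of 0.10 with sgRNA (camera adjusted p = 0.0164; adjusted p = 0.379 with an estimated correlation) and 0.06 over all guides (0.0304; adjusted p = 0.557 with an estimated correlation). Genes typical of HEK293 cells had medians of 0.07 with sgRNA (0.0365), 0.11 with TOP1 (0.0148) and 0.08 over all guides (0.0418); an estimated correlation gave adjusted p-values of 0.322, 0.386 and 0.557. NEFL, a neurofilament gene of that list, was at 17.2 FPKM in CasVP (SD 1.02) and 21.6 with TOP1 (SD 2.90) without passing. Sterol synthesis genes had medians of 0.06 with INT (0.0248) and 0.04 over all guides (0.0477), and hypoxia and glycolysis genes 0.05 with INT (0.0222) and 0.02 over all guides (0.0418). With an estimated correlation these gave adjusted p-values of 0.549, 0.762, 0.441 and 0.564. The sterol call over all guides also ended with a replicate block (0.0821) and after removal of length and GC trends (0.103). In INT against sgRNA, unfolded protein response genes had a median of -0.07 (0.0216; adjusted p = 0.395 with an estimated correlation) and cell cycle genes -0.05 (0.0454; adjusted p = 0.637 with an estimated correlation), and both medians turned above 0 with quantile normalization. No member of these lists passed in these comparisons, over all genes or adjusted over the list alone. NF-kappaB and heat shock lists passed in no comparison with all libraries; their lowest camera adjusted p-values were 0.285 and 0.124.

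Without CasVP replicate 0, list calls ended for immediate early genes (adjusted p = 0.0919 with sgRNA, 0.132 over all guides), for genes typical of HEK293 cells (0.0919 with sgRNA, 0.0503 with TOP1, 0.132 over all guides) and for sterol genes (0.444 with INT, 0.732 over all guides). Hypoxia genes over all guides then had 0.07. Without INT replicate 0, sterol (0.303) and hypoxia genes (0.436) lost their call with INT, and all 4 lists over all guides had 0.0806. The HEK293 list with sgRNA also lost its call without sgRNA replicate 0 (0.0571) or 1 (0.0539). Over all guides, sterol genes lost it without P4P6 replicate 1 (0.411), TOP1 replicate 1 (0.143) or sgRNA replicate 1 (0.148), and hypoxia genes without CasVP replicate 1 (0.0891), P4P6 replicate 1 (0.163) or TOP1 replicate 1 (0.0661). For unfolded protein response genes in INT against sgRNA the call ended without INT replicate 1 (0.138) or sgRNA replicate 0 (0.118). Cell cycle genes lost theirs there without CasVP replicate 0 (0.0523) or 1 (0.0522), INT replicate 0 (0.144) or 1 (0.0658), or sgRNA replicate 0 (0.109) or 1 (0.103). Heat shock genes gained a call without CasVP replicate 1 (0.0102 with sgRNA, 0.0375 with TOP1 and over all guides) and, in P4P6 against sgRNA, without P4P6 replicate 1 (0.0259).

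Leaving out a library gained 44 list calls in all. With sgRNA against CasVP, interferon genes gained one without CasVP replicate 1 (adjusted p = 0.0125) or INT replicate 0 (0.0452) or 1 (0.0452), histone genes, lower, without sgRNA replicate 1 (0.000226) and sterol genes without CasVP replicate 1 (0.00338) or sgRNA replicate 0 (0.00545). With INT, interferon genes did so without CasVP replicate 1 (0.0229) or INT replicate 0 (0.0433), and immediate early genes without CasVP replicate 1 (0.0446), INT replicate 1 (0.0334) or TOP1 replicate 0 (0.0324) or 1 (0.0325). Genes typical of HEK293 cells passed there without any single library except CasVP replicate 0 and INT replicate 0 (0.0113 to 0.0497). In P4P6 against CasVP, sterol (0.00410), hypoxia (0.0396) and cell cycle genes (0.0258, lower) passed without P4P6 replicate 0. With TOP1, hypoxia genes passed without TOP1 replicate 0 (0.0371) and immediate early genes without TOP1 replicate 1 (0.00847). Over all guides, histone genes passed, lower, without CasVP replicate 0 (0.0263), INT replicate 1 (0.0412), TOP1 replicate 0 (0.0396) or sgRNA replicate 1 (0.00419). Histone genes were also lower without sgRNA replicate 0 in INT (6.06e-05) and P4P6 against sgRNA (0.0473). In TOP1 against sgRNA they were higher without sgRNA replicate 1 (2.92e-06), p53 targets were lower without TOP1 replicate 0 (0.0105) or sgRNA replicate 1 (0.00559), and immediate early genes were lower without TOP1 replicate 0 (0.000817).

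Markers of other cell types were near or below 1 FPKM in most cases. Of the fibroblast list, 3 of 11 matched genes were tested, with FBLN1, an extracellular matrix gene, highest at a mean of 17.2 FPKM. CD68 at 1.03 FPKM was the only blood marker tested and EPCAM at 1.35 the only epithelial one. Endogenous genes often targeted by dCas9 activators elsewhere did not pass in any comparison, with VEGFA highest at a mean of 49.5 FPKM beside KLF4, CXCR4 and SOX2. Mitochondrially encoded and short non-polyadenylated RNAs matched 0 features by name, and MEG3, the single nuclear long non-coding RNA matched, was listed at 0.

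Many small differences separated P4P6 from sgRNA. A bias by transcript length or GC content could account for part of the count. Changes correlated across 9936 genes with GC content (Spearman's rho 0.385) and length (0.190). Removing both trends turned 1092 calls into 216, of which 187 were among the 1092 (17.1%). The count over all tested features also fell to 384 with library weights and 668 without the intensity trend. A fall in calls alone therefore does not single out such a bias. Over 1121 called genes the median absolute difference shrank from 0.25 to 0.18 while the median SD stayed at 0.05, so that fewer genes passed. These genes were picked for being called, so part of the shrinkage may come from that choice. Differences from library pairs that share no library correlated by 0.292 and 0.514 across genes. A single library as the only source would leave them unrelated, so both values go against that. The lower value fell short of the bound set beforehand, so a part played by a single library stays open. A change brought by the P4P6 guide alone, the biological explanation, cannot be told apart from variation between groups. With sgRNA at 0 and P4P6 at 1, INT lay at 0.568 (0.365 to 0.742 over 4 choices of libraries), CasVP at 0.307 (0.143 to 0.477) and TOP1 at -0.28 (-0.621 to 0.0168).

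A hypothesis is that p53 targets may respond to a guide, since their score was 0.16 higher in guide libraries than in CasVP. Not every guide library showed this: P4P6 replicate 1 had the lowest score of all, -0.19, and the median change in P4P6 against sgRNA was -0.13. Chance variation of genes that vary together could give this: 5 of 45 splits gave a difference as large, the highest other being 0.22, and the exact permutation p adjusted over 13 lists was 0.433. Of the 25 splits with 1 library of each index, 2 gave a difference as large. Removing length and GC trends left 0.986 of the difference, which argues against them. The dCas9-VP64 level cannot be told apart from the other explanations. Over the 8 guide libraries the slope of the score on log2 dCas9-VP64 was 0.0305 (95% confidence interval -0.384 to 0.445), an interval that holds both 0 and the 0.333 that would give the whole difference from CasVP. The response to a guide, the biological explanation, stays open beside chance and the dCas9-VP64 level.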
